A study of Arabidopsis thaliana with 32 samples.

How the data were processed

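Leaves of Arabidopsis thaliana Col-0 plants were profiled on 32 Affymetrix whole-genome arrays, 1 RNA preparation per array, with 22810 probe sets each. The groups were read from the treatment text in the labels, since the titles hold only a number. There were 16 groups of 2 arrays: untreated leaves, and leaves taken 4, 8, 16, 24 and 48 h after injection of a MgCl2 mock solution, of Pseudomonas syringae ES4326 (called virulent here) or of the same strain carrying the effector gene avrRpt2 (called avirulent). The bacterial dose is not given in the sources used here. Nothing in the labels says whether the 2 arrays of a group came from separate experiments, so p-values measure the spread between these arrays, which may be technical.

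The deposited values are signal intensity on a linear scale made with MAS5, per the submitters' processing notes, which give no version. Their trimmed mean lay between 99.2 and 99.4 on every array, so the authors' intensity values had been scaled to a common mean before they were deposited. No column was left unused. The number of arrays limits the precision of every value below.

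The 64 control probe sets were left out of all tests. A probe set was kept if its signal reached 22.2, the 40th percentile of all values, on at least 2 arrays, which kept 16188. Tests used log2(signal + 6.82), the added constant being the 20th percentile of all values, so fold changes of dim genes are understated. Group means were fitted to all 32 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, 16 residual degrees of freedom), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were each strain against mock and the strains against each other at each of the 5 times and in the mean over times, mock over all times against untreated, and the change of each effect from 4 h to each later time. Figures were drawn with matplotlib 3.10.9. Values after a ± sign are SDs over 2 arrays unless they are named as SE.

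Gene names came from the array's annotation table, updated through a gene table. It gives 1 gene for 13513 probe sets (13436 with a locus in the gene table) and several for 503, and 8730 probe sets are unnamed here. Among the kept probe sets 9015 have 1 gene, 317 several and 6856 none. No gene was named from outside these tables, so many well-known defence genes could not be followed. Of 37 genes fixed as markers before the data were examined, 3 were measured. No genome was used and no coordinates are given.

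The choices fixed before the data were examined were the tests, the filter, the rule for named genes and 27 gene lists, of whose 432 members 53 were measured. A list was tested if at least 3 members were measured, which held for 8 of the 27. A further 23 lists, of which 18 could be tested, were written after the annotation had been read and before any test was run; each is called an added list. The 26 lists were tested with camera (preset correlation 0.01, and again with an estimated correlation), with adjustment over all lists and times of a pair of treatments, which made 130 tests per pair. Each gene was represented by its brightest probe set. No list call of any comparison held with an estimated correlation, so every list result below rests on the preset one.

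The rule for named genes took the 3 measured markers; for each pair of treatments the 5 largest rises and falls in the mean over times among called probe sets with 1 gene and the same sign in both runs of array numbers; up to 3 members per list and pair, at the time with most called members; up to 4 rises and falls per time between strains; 5 rises and falls of mock against untreated; and reference genes. Genes named outside this rule are said to be so, and were chosen after their values were seen. The array numbers in the titles fall into 2 runs, 2503 to 2530 and 2783 to 2798, each with 1 array of every group. The first breaks into 2503 to 2512 (10 arrays) and 2525 to 2530 (6 arrays). These 6 are the virulent arrays and 1 mock array (16 h), so that within the first run virulent and mock arrays stand apart at 4, 8, 24 and 48 h, as do avirulent and mock arrays at 16 h. Virulent and avirulent arrays of the first run stand apart at every time. A block with these 3 levels was therefore added after the data had been seen.

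Alternatives planned in advance were the 2 runs as a block, quantile normalization, a constant of 1 or at the 40th percentile, no filter, a fit to the arrays of 1 time alone, and leaving out each array in turn. The procedure was tested on simulated data with 200 changed probe sets among 16188. Normal noise with the fitted variances was drawn independently for each array and probe set, with no effect of the number runs. The figures that follow are therefore not the error rates of the real comparisons. For virulent against mock at 24 h it recovered 50.0% of 2-fold changes (5 false calls) and 96.5% of 4-fold changes (6 false calls). For avirulent against mock at 16 h it recovered 50.5% of 2-fold changes (1 false call) and 93.5% of 4-fold changes (11 false calls). For virulent against mock in the mean over times it recovered 96.5% of 2-fold changes (8 false calls) and all 4-fold changes (9 false calls).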

Results

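The arrays compared the response of Arabidopsis leaves to a virulent bacterium with that to the same bacterium carrying avrRpt2, an effector that Col-0 plants recognise through the resistance protein RPS2. Median signals ranged from 33.9 to 39.4 between arrays, and the 2 arrays of a group correlated with r between 0.953 and 0.978 across probe sets. The 3 measured reference genes did not pass the test in either strain against mock at 16 h, at 24 h or in the mean over times: PEX4 (AT5G25760) had log2 fold changes of -0.07 for the virulent strain at 24 h and -0.06 for the avirulent strain at 16 h, with an SE of 0.15 (n = 2 arrays per group, limma adjusted p = 0.800 and 0.842). The largest value among these genes was that of AT4G34270 for the virulent strain at 24 h, a log2 fold change of 0.53 (SE 0.23, limma adjusted p = 0.137). The actin 3' to 5' control ratio was not even: in the run numbered 2783 to 2798 it was 3.24 ± 2.07 on mock arrays, 7.25 ± 1.02 on virulent and 7.19 ± 0.801 on avirulent arrays (SD, n = 5 each), and in the other run the means were 6.14, 5.03 and 6.90. The GAPDH ratio was 1.45 ± 0.109, 1.48 ± 0.172 and 1.51 ± 0.182 in the run numbered 2783 to 2798.

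The first question was what the virulent strain changed against mock. In the mean over times the largest rises among named genes were those of AT3G13610, a feruloyl-CoA hydroxylase of coumarin synthesis, with a log2 fold change of 1.92 (SE 0.49, limma adjusted p = 0.00750), and of UGT76B1 (AT3G11340), a glucosyltransferase acting on immune signal molecules, with 1.80 (SE 0.43, adjusted p = 0.00496). AT3G28510, an AAA-type ATPase, rose by 1.78, AT1G68620, a carboxylesterase-like protein, by 1.67 and AT4G39670, a glycolipid transfer protein family member, by 1.62. The largest falls among named genes were those of the expansin gene EXPA8 (AT2G40610) at -1.34 (SE 0.19), the lipase-like gene AT4G18970 at -1.32, the cytokinin response regulator gene RR16 (AT2G40670) at -1.28, AT2G10940 at -1.18 and DRT100 (AT3G12610) at -1.15. Among probe sets with no gene name, values reached 2.13 and -1.83. The mock means of AT3G13610, UGT76B1, AT3G28510 and AT1G68620 lay under the filter's floor of 22.2 at 3, 3, 4 and 4 of the 5 times, so the sizes of these rises depend on the added constant. In all, 3834 of 16188 probe sets were called, 1651 higher and 2183 lower, of which 141 changed at least 2-fold. Of the called probe sets 3833 had the same sign in both runs of array numbers. That is nearly given by the selection, since the calls rest on the mean of the same runs. All 10 genes named here stayed called without any 1 of the 20 arrays. With the block of 3 number runs, added after the data had been seen, 2306 were called, 2124 of them among the 3834.

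At 24 h the virulent strain had its highest count, and some genes of immune perception and signalling rose. WRKY53 (AT4G23810), a transcription factor gene of early defence, reached a signal of 494 ± 58.7 against 97.6 ± 30.6 in mock (SD, n = 2), a log2 fold change of 2.29 (SE 0.44, limma adjusted p = 0.00252). EFR (AT5G20480), the receptor for bacterial elongation factor Tu, had 37.3 ± 1.63 against 8.41 ± 6.85, a value under the floor, and WRKY6 81.3 ± 1.96 against 32.5 ± 0.336. Of the 9 measured members of the pattern-triggered immunity list 4 rose and none fell (6 rose when adjusted over the list alone; median log2 fold change 0.97; camera adjusted p = 0.00108, and adjusted p = 0.592 with an estimated correlation). At 16 h GRX480 (AT1G28480), a glutaredoxin gene of salicylic acid signalling, rose to 507 ± 63.3 against 117 ± 44.5 in mock and SAG101, a partner of EDS1, rose by 0.87, and AT5G52810, a reductase of pipecolic acid synthesis, rose at 24 h by 1.85. SGT1A, a co-chaperone of intracellular receptors, rose at 24 h by 1.62 and NDB2, an alternative mitochondrial NADH dehydrogenase, by 2.15.

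Of the 18 genes in the list of protein folding in the endoplasmic reticulum 3 were measured, and these 3 rose and were called at 24 h. They were also called when adjusted over the list alone (median log2 fold change 1.56, camera adjusted p = 7.78e-04, and adjusted p = 0.592 with an estimated correlation). ATERDJ3B, an endoplasmic reticulum co-chaperone, had a log2 fold change of 1.79, the calreticulin gene CRT1b 1.56 and BZIP60, a transcription factor gene of the unfolded protein response, 1.08. Of 35 members of the added list of secretory pathway machinery 5 rose and none fell (median 0.33; camera adjusted p = 3.42e-05, and adjusted p = 0.592 with an estimated correlation). Of 49 genes of TIR domain proteins, also an added list, 8 rose and none fell (median 0.18; camera adjusted p = 0.0201, and adjusted p = 0.632 with an estimated correlation); without virulent replicate 1 the list's adjusted p was 0.173. The calcium sensor genes CML41 and CML37 rose by 2.50 and 2.42, the largest of 7 calmodulin-like genes; that added list did not pass (camera adjusted p = 0.0813).

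Some photosynthesis genes fell at 24 h. The antenna gene LHCB4.2 had a log2 fold change of -0.62 (SE 0.19, limma adjusted p = 0.0357) and PSAN, a photosystem I subunit, -0.49. Of 7 measured members of the list 2 fell and none rose (3 fell when adjusted over the list alone), and the list did not pass at 24 h (median -0.27, camera adjusted p = 0.101). SBPASE of the Calvin cycle fell by 0.66 and was the 1 of 3 carbon fixation genes called. CHLM, a methyltransferase of chlorophyll synthesis, fell by 0.69 at 16 h. Of 107 cytosolic ribosomal protein genes, an added list, 7 fell and none rose (none when adjusted over the list alone; median -0.23; camera adjusted p = 0.00194, and adjusted p = 0.799 with an estimated correlation); without mock replicate 1 the list's adjusted p was 0.182. Among all 16188 probe sets 1044 fell and 1131 rose at 24 h, with a median of -0.085. The 7 of 107 that fell thus lie near the share of all probe sets. With the block of 3 number runs LHCB4.2, PSAN and EFR were no longer called. Of the 39 genes called at 24 h under the rule, 11 stayed called without any 1 of the 4 arrays, among them WRKY53, SGT1A, CML41, CML37 and the 3 folding genes; none of the 6 at 16 h did.

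Over time, the virulent strain differed from mock in 1 probe set at 4 h, 0 at 8 h, 220 at 16 h (92 higher, 128 lower), 2175 at 24 h (1131 higher, 1044 lower) and 18 at 48 h, by limma. At an unadjusted p under 0.05 there were 806 at 8 h. That is about the share of 0.05 of the 16188 tested that chance alone would give. The 1 at 4 h was AT2G43250, with a log2 fold change of 1.44 (SE 0.22), a gene outside the rule and chosen after its values were seen. With the block of 2 number runs the 16 h count was 927 and with 3 number runs 1082. Leaving out any 1 of the 4 arrays left 0 to 3 at 16 h. At 24 h it left 619 without mock replicate 1, 652 without mock replicate 2, 1172 without virulent replicate 1 and 659 without virulent replicate 2. At 48 h it left 898 without virulent replicate 2, 0 without virulent replicate 1, and 3 and 2 without mock replicates 1 and 2. At 4 h it left 21 without virulent replicate 1 and 0 or 1 without another array.

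**Figure D1:**
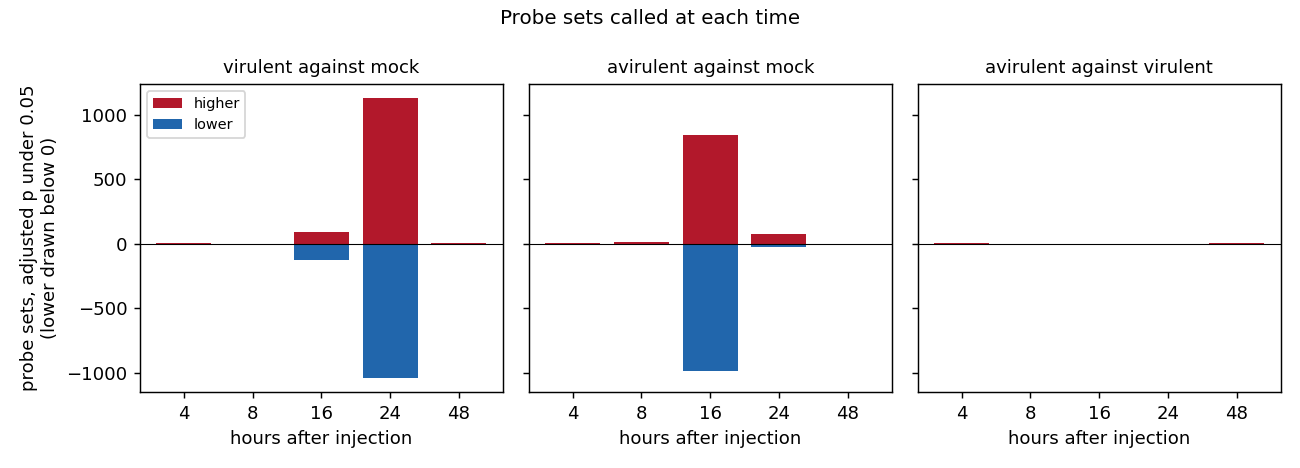
Probe sets with adjusted p under 0.05 at each time in hours after injection, for 3 comparisons; bars above 0 count higher and bars below 0 lower probe sets. The virulent strain had 2175 at 24 h and 220 at 16 h, the avirulent strain 101 and 1825, and the strains differed from each other in at most 9 at any time.

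The second question was what the avirulent strain changed against mock. Among named genes the same 3 led the rises in the mean over times, again with the limit that their mock signals were near the floor: AT3G13610 rose by 2.50 on the log2 scale (SE 0.49, limma adjusted p = 0.00109), UGT76B1 rose 4.94-fold and AT3G28510 4.01-fold, followed by AT1G57630, a TIR domain protein gene, by 1.98 and AT4G01870, whose mock mean lay under the floor at 3 of the 5 times, by 1.85 on the log2 scale. AT2G10940 fell by 1.44, the lipase-like gene AT4G26790 by 1.28, AT5G13140 by 1.21, DRT100 by 1.15 and AT3G07540 by 1.11. The avirulent means of AT3G07540 and AT4G26790 lay under the floor at 5 and 4 of the 5 times, so these sizes depend on the added constant. Among probe sets with no gene name, values reached 2.85 and -1.81. The test called 3382 probe sets, 1603 higher and 1779 lower, 203 of them at least 2-fold, and all 10 genes named here stayed called without any 1 of the 20 arrays. With the block of 3 number runs 4601 were called.

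At 16 h the avirulent strain had its highest count. WRKY53 stood at 434 ± 55.4 against 145 ± 9.45 in mock (SD, n = 2), a log2 fold change of 1.54 (SE 0.44, limma adjusted p = 0.0267), and PUB24, a ubiquitin ligase gene of immune signalling, at 268 ± 16.9 against 115 ± 18.7. Of 9 pattern-triggered immunity genes 2 rose (3 when adjusted over the list alone), and the list did not pass at 16 h (median 0.33, camera adjusted p = 0.0838). GRX480 rose by 2.02, SAG101 by 0.99, SGT1A by 1.35, NDB2 by 1.47, CML37 by 1.62 and CML41 by 1.54. All 3 measured endoplasmic reticulum folding genes rose (3 when adjusted over the list alone), ATERDJ3B to 1144 ± 82.9 against 460 ± 22.5, CRT1b by 1.22 and BZIP60 by 0.78 (camera adjusted p = 0.00702, and adjusted p = 0.539 with an estimated correlation). Of the added lists, 6 of 35 secretory pathway genes rose (median 0.35; camera adjusted p = 1.58e-04, and adjusted p = 0.587 with an estimated correlation) and 6 of 49 TIR domain genes (median 0.31; camera adjusted p = 1.89e-04, and adjusted p = 0.469 with an estimated correlation).

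Of 18 expansin and xyloglucan endotransglucosylase genes, an added list, 2 fell at 16 h and none rose (2 when adjusted over the list alone). The list did not pass (median -0.36, camera adjusted p = 0.153). EXPA8 stood at 82.0 ± 35.7 against 343 ± 155 in mock (SD, n = 2), a log2 fold change of -1.97 (SE 0.44, limma adjusted p = 0.00883), and XTH32, a cell wall xyloglucan enzyme gene, at 43.6 ± 10.6 against 91.9 ± 11.6. PSAN fell by 0.48, SBPASE by 0.77 and CHLM by 0.83. Of 7 photosystem genes 1 fell (1 when adjusted over the list alone), with a list median of -0.31 (camera adjusted p = 0.0161, and adjusted p = 0.719 with an estimated correlation). STOMAGEN, a secreted peptide gene that promotes stomata formation, fell by 1.74, and the sugar transporter gene SWEET2 by 0.82.

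The avirulent strain differed from mock in 5 probe sets at 4 h, 11 at 8 h, 1825 at 16 h (839 higher, 986 lower), 101 at 24 h and 1 at 48 h, by limma. Outside the rule, and chosen after their values were seen, AT2G43250 rose at 4 h by 1.94, AT4G01870 at 8 h by 2.55, and AT1G71710 fell at 48 h by 1.15. Without avirulent replicate 1 the 16 h count was 1, without mock replicate 1 it was 284, without mock replicate 2 it was 786 and without avirulent replicate 2 it was 1211. None of the 35 genes called at 16 h under the rule stayed called without each of the 4 arrays in turn, avirulent replicate 1 ending every one of these calls. Leaving out any 1 array left 0 to 5 at 24 h, 0 to 5 at 8 h and 0 to 3 at 48 h, and at 4 h 34 without avirulent replicate 2; with 2 number runs as a block the 16 h and 24 h counts were 2758 and 374, and with 3 number runs 2894 and 521.

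The third question was whether the strains differed from each other. At 48 h 4 named genes did. AT4G33150, which encodes the bifunctional lysine-degrading enzyme, was lower in avirulent (59.5 ± 5.90) than in virulent leaves (154 ± 29.4; SD, n = 2), a log2 fold change of -1.26 (SE 0.19, limma adjusted p = 0.00488). AT5G39520 stood at 22.7 ± 8.82 against 167 ± 51.1 and the aldehyde dehydrogenase gene ALDH7B4 at 228 ± 47.1 against 532 ± 60.2. The sugar transporter gene SWEET3 was higher, at 33.9 ± 11.0 against 2.75 ± 2.06, the lower value being under the filter's floor. In all 9 probe sets were called at 48 h, 2 higher and 7 lower; with the block of 3 number runs 3 were called, AT4G33150 among them and the other 3 named genes not. Without virulent replicate 1 or avirulent replicate 2 the count was 0, without avirulent replicate 1 it was 14 and without virulent replicate 2 it was 65.

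At the other times few or no differences between strains passed. The counts were 1 at 4 h, 0 at 8 h, 0 at 16 h, 0 at 24 h and 0 in the mean over times by limma. At an unadjusted p under 0.05 there were 469, 564, 1327 and 1401 at 8 h, 16 h, 24 h and in the mean. Chance alone would give a share of 0.05 of the 16188 tested. The counts at 8 h and 16 h lay below that share and those at 24 h and in the mean above it. The excess was not tested. The 1 at 4 h has no gene name here; without avirulent replicate 2 the 4 h count was 11 and without virulent replicate 1 it was 6, and without virulent replicate 1 the 24 h count was 10. The measured marker PDF1.2 (AT5G44420) is a defensin gene of the jasmonate and ethylene response. Its signal at 24 h was 200 ± 6.96 in avirulent, 9.86 ± 0.830 in virulent and 27.8 ± 31.8 in mock leaves (SD, n = 2). The virulent mean lay under the floor. The limma adjusted p was 0.577 between strains and 0.153 for avirulent against mock. With the block of 3 number runs the difference from mock passed (limma adjusted p = 0.0290) and that between strains did not (0.326). The markers BSMT1, a methyltransferase for salicylic acid, and SWEET10 did not pass at any time in either strain. All group means of SWEET10 lay under the floor. The 2 arrays of a group differed widely for BSMT1 in places, with 2.99 and 60.2 in mock at 4 h. These results therefore do not show that the 2 genes were unchanged. At 24 h the endoplasmic reticulum folding list was lower in avirulent than in virulent leaves (median -0.82, 0 of 3 members called, 3 lower when adjusted over the list alone; camera adjusted p = 0.00231, and adjusted p = 0.882 with an estimated correlation), as was the added secretory list (median -0.19; camera adjusted p = 1.49e-04, and adjusted p = 0.882 with an estimated correlation).

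**Figure D2:**
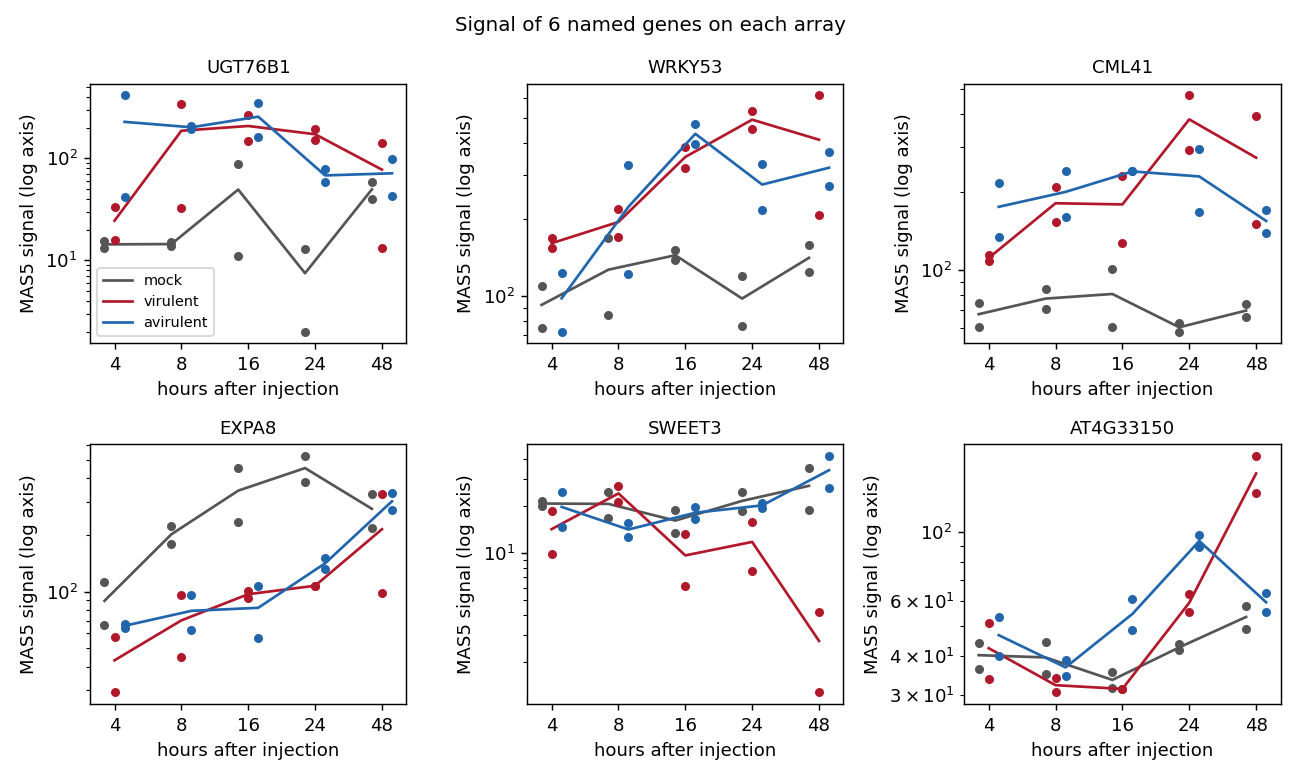
MAS5 signal (log axis) of 6 named genes against hours after injection; each point is 1 array and each line joins the arithmetic means of the 2 arrays of a group. For AT4G33150 at 48 h the virulent mean is 154 and the avirulent mean 59.5; for EXPA8 at 16 h the avirulent mean is 82.0 and the mock mean 343.

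The 2 responses were then set against each other over time. Of the probe sets that rose with the avirulent strain at 16 h (839), 577 also rose with the virulent strain at 24 h, where independent lists would share 58.6; of the 986 that fell, 542 also fell, against 63.6. None was called in opposite directions. These comparisons share no array, but they come from the same fit, which gives each probe set the same variance in both. The lists are therefore not fully independent, and the numbers for independent lists are only a reference. Across probe sets, which are not independent replicates, the effects at 16 h correlated with r = 0.842 between strains (covariance 0.182), but they share the mock arrays, which alone gave r = 0.500 and a covariance of 0.0420 in simulated unchanged groups. The observed covariance exceeded that one by 0.140, and part of the excess may still come from the shared controls. When the 2 effects were taken from different number runs, and so shared no array, avirulent at 16 h correlated with virulent at 24 h with r = 0.564 and 0.657, and with virulent at 16 h with r = 0.520 and 0.493. The virulent effect at 24 h was also the most repeatable between runs (r = 0.713, against 0.527 at 16 h). The avirulent effect had r = 0.617 between runs at 24 h and 0.522 at 16 h. After division by repeatability, an alternative added after the data had been seen, the value with 16 h was 0.966 and that with 24 h was higher by 0.0347. Both lay near 1, the ceiling of this measure, so it does not rank the times. In the other direction, virulent at 24 h was closer to avirulent at 24 h (r = 0.593) than at 16 h (0.564) with the avirulent effect from the first run, and closer to 16 h (0.657, against 0.600) with it from the second. Over the 12 contrasts of later times with 4 h, 1 probe set was called, AT2G43250. The contrast of 24 h with 16 h between strains, added after the data had been seen, called 0 probe sets by limma, with 925 at an unadjusted p under 0.05. That is not far above the share of 0.05 of the 16188 tested that chance alone would give. The same contrast within each strain, also added after the data had been seen, called 0 probe sets. At an unadjusted p under 0.05 it gave 693 for the virulent and 353 for the avirulent effect, both below that share.

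**Figure D3:**
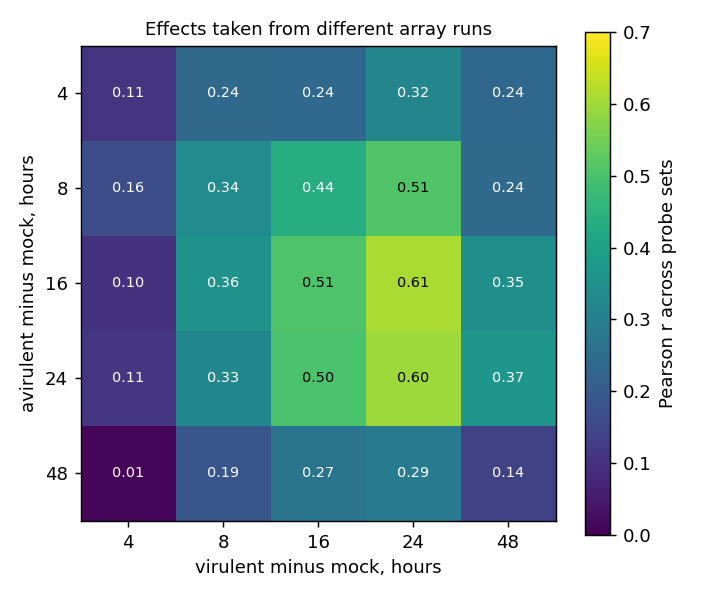
Pearson r across probe sets between the avirulent effect (vertical axis, hours) and the virulent effect (horizontal axis, hours), each minus mock, averaged over the 2 ways of taking them from different number runs, so that no array is shared. The value is 0.610 for avirulent 16 h with virulent 24 h and 0.506 with virulent 16 h, and the virulent 24 h column holds the highest value of each row.

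The last comparison set mock leaves, averaged over all times, against untreated leaves, and so mixes injection with the time since injection. GI (AT1G22770), a clock-regulated gene, fell by 2.49 (SE 0.46, limma adjusted p = 0.00402), COR15B, a cold-regulated gene, by 2.16, AT2G20670 by 1.97, AT5G19120 by 1.78 and AT4G15690, whose mock means all lay under the floor, by 1.73. AT5G47330 rose by 1.98, AT2G36970 by 1.68, AT2G16630 by 1.38, AT2G19650 by 1.26 and RR16 by 1.25. The signal of COR15B in mock leaves was 1821 ± 177 at 4 h and 137 ± 8.00 at 48 h, against 1924 ± 419 in untreated leaves (SD, n = 2). RR16 had 68.7 ± 34.0 at 4 h and 186 ± 57.5 at 48 h, against 49.6 ± 1.24. In all 492 probe sets were called, 256 higher and 236 lower. Of 7 photosystem genes 1 fell (4 when adjusted over the list alone; median -0.30; camera adjusted p = 3.50e-04, and adjusted p = 0.610 with an estimated correlation). The hour at which untreated leaves were taken is not given in the sources used here, and without untreated replicate 1 the count was 307 and without untreated replicate 2 it was 205. Of the 10 named genes COR15B and AT2G36970 stayed called without any 1 of the 12 arrays; GI was not called without untreated replicate 2 (limma adjusted p = 0.154). With the block of 2 number runs the count was 1033 and with 3 number runs 1146.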

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

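The tests of pairs of times other than those with 4 h, and that of a shared change from 24 h to 48 h, were chosen only after results had been seen. The difference between times was tested directly (limma, adjusted within each contrast), since groups of 2 arrays are too small for a test of single outlying arrays. AT2G43250 fell by 2.57 from 4 h to 48 h in its avirulent effect. AT4G33150 had a virulent effect 1.65 higher at 48 h than at 8 h. The difference between strains at 48 h set against earlier times gave the rest. For AT4G33150 it was -1.94 against 16 h and -1.87 against 24 h, for AT5G39520 -3.82 against 16 h, and for AT4G01870 -4.06 against 24 h. Among probe sets with no gene name, 2 differed against 8 h (-2.46 and -2.63), 4 against 16 h (-3.10, -3.25, -1.33 and 1.23) and 10 against 24 h (-3.12, -3.70, -1.67, -1.07, -2.69, -2.64, -2.18, -3.89, -2.56 and -2.25). Of 312 tests of list differences between times, 32 passed with the preset correlation and 0 with an estimated one.

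The virulent arrays at 48 h stand apart, and the 48 h differences rest on them; the avirulent pair at 4 h stands as far apart (r = 0.953 between replicates in both), its second-run effect having r = 0.474 with the first run's virulent effect at 24 h and 0.239 with its own time. The effect of the array in the first number run correlated with r = 0.633 with the second run's virulent effect at 24 h and with r = 0.230 with that at 48 h, a gap of 0.404, as a wrong time label on that array would give. Against a 24 h label, COR15B, which fell with time, stood at 113 on that array, 81.5 to 142 on the other 5 arrays at 48 h and 157 to 248 on the 6 at 24 h, and AT4G33150 and ALDH7B4, both chosen for their 48 h values, stood at 174 and 574 there, 133 and 489 on the other virulent 48 h array, and 63.0 and 327 on the first-run virulent array at 24 h. Along the probe sets that changed most from 24 h to 48 h in mock and avirulent leaves (50 to 500 probe sets) the array lay 0.26 to 0.57 beyond the virulent 24 h mean on the log2 scale, toward 48 h, but the same procedure put the mock 48 h arrays -0.14 to -0.02 from their 24 h mean and so does not tell known times apart. The other 3 first-run virulent effects before 24 h were also closest to the second run's 24 h effect. AT4G33150 and ALDH7B4 exclude nothing, since both were chosen for their 48 h values. COR15B was named for its difference between mock and untreated leaves, but 1 gene on 1 array does not settle the label. A wrong label and a difference in the course of infection between the plants therefore cannot be told apart with 2 arrays.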

How the results depend on the processing

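The block of 3 number runs was added after seeing the data, and the cause of the moves below was not tested. The labels do not say that the 2 number runs pair the arrays. Differences between the first-run and second-run array correlated over pairs of groups with r between -0.164 and 0.435 (median 0.214), above 0.1 in 96 of 120. Arrays of a run thus shared part of their deviation, which the main fit does not take into account. Leaving out an array leaves a lone array that is assumed to vary like the other groups. Dim genes are limited by signal over background, 57.2% to 63.2% of probe sets lying over the floor. With the block of 2 runs, virulent against mock gave 927 probe sets at 16 h and 50 at 48 h, avirulent against mock 23, 36, 2758 and 374 at 4, 8, 16 and 24 h, the strains 4 at 4 h, and mock against untreated 1033. With 3 runs, virulent against mock gave 1082 at 16 h, 11 at 48 h and 2306 in the mean, avirulent against mock 22, 49, 2894 and 521, the strains 3 at 48 h, and mock against untreated 1146. From the arrays of 1 time alone, virulent against mock gave 0, 825 and 2 at 4, 16 and 48 h, avirulent against mock 0, 747 and 0 at 4, 24 and 48 h, and the strains 0 and 2 at 4 and 48 h. With no filter virulent against mock gave 3 and 91 at 4 and 16 h, avirulent against mock 7 at 8 h and the strains 1 in the mean. A constant of 1 gave 1 (virulent, 8 h) and 7 (avirulent, 8 h); one at the 40th percentile gave 0 (virulent, 4 h), 8 and 7 (avirulent, 4 and 8 h) and 1 (strains, mean). Quantile normalization gave 9 (virulent, 48 h) and 11 (avirulent, 4 h). The 1 probe set over the 12 contrasts with 4 h became 6 with 2 runs, 18 with 3, and 3 with either constant.

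Leaving out each array in turn gave, for virulent against mock, 0 to 21 at 4 h, 0 to 2 at 8 h, 0 to 3 at 16 h, 619 to 1172 at 24 h, 0 to 898 at 48 h and 2661 to 4555 in the mean. For avirulent against mock it gave 1 to 34, 0 to 5, 1 to 1211, 0 to 5, 0 to 3 and 2680 to 3672. For the strains it gave 0 to 11, 0 to 3, 0 to 1, 0 to 10, 0 to 65 and 0 to 1, and for mock against untreated 205 to 459. Named genes called against mock in the mean over times kept their calls in every such refit. Most of the named genes called at a single time lost theirs in at least 1. List calls turned direction in 3 refits: cytosolic ribosomal proteins between strains in the mean with 3 runs (adjusted p = 0.454) and at 48 h without avirulent replicate 2 (0.876; 5.13e-11 without replicate 1), and chloroplast photosystem genes between strains at 8 h without avirulent replicate 2 (0.622; 1.91e-07 without replicate 1). With the actin covariate 3799 probe sets were called for the virulent and 2854 for the avirulent strain in the mean. Of these, 3320 and 2541 were among the 3834 and 3382 called without it, in the same direction.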

Other observations

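The contrasts of 24 h with 16 h between and within strains, the block of 3 number runs, with all arrays and without each, and the actin covariate were tests added after the data had been seen. Single members of several enzyme families, all from added lists, passed the test with infection. Of 28 measured UDP-glycosyltransferase genes 4 rose and 1 fell with the virulent strain at 24 h (camera adjusted p = 0.877); with the avirulent strain at 16 h UGT73D1 rose by 2.04 and UGT87A2 by 1.95, while UGT85A4 fell by 0.73. Glutathione transferase genes that were called fell: GSTU20 by 1.11 and GSTU18 by 0.76 with the avirulent strain at 16 h. Among serine carboxypeptidase-like genes at 24 h with the virulent strain scpl16 rose by 1.41, and scpl50 and scpl25 fell by 1.05 and 0.96. OPCL1, a ligase of jasmonate synthesis, rose by 1.15 with the virulent strain at 16 h. The chloroplast-encoded genes rps16 and rpl32 fell by 1.43 and 0.78 with the virulent strain at 24 h; their list of 19 had a median of -0.61 (camera adjusted p = 0.0323, and adjusted p = 0.632 with an estimated correlation; 0.124 without virulent replicate 2 and 0.0506 without mock replicate 1). The call of rpl32 ended with the block of 3 number runs, and none of the calls given with a fold change in this paragraph held without each of the 4 arrays in turn.

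The avirulent strain had its highest count at 16 h (1825, and 101 at 24 h) and the virulent at 24 h, but the avirulent count at 16 h was 1 without avirulent 16 h replicate 1, and 284, 786 and 1211 without mock replicates 1 and 2 and avirulent replicate 2. Whether the breaks in the array numbers gave this order stays open. Within the arrays numbered 2783 to 2798 alone, the SD across probe sets of the avirulent effect at 16 h was divided by that at 24 h. The result was 1.33 times the same ratio for the virulent effect, which speaks against the breaks, but single arrays give it no spread. With the block of 3 number runs the order held (2894 and 521 for the avirulent strain, 1082 and 2022 for the virulent). It was lost for the virulent strain without virulent 24 h replicate 1 and without mock 24 h replicate 1 or 2. Leaving out any other array of 16 h or 24 h kept it, but in some fits only barely. Without avirulent 16 h replicate 1 the avirulent counts at 16 h and 24 h were nearly equal. The same held for the virulent counts without virulent 24 h replicate 2. Counts also fall because fewer arrays are left, so the losses alone do not speak for the breaks. The higher avirulent count at 16 h did not go with better repeatability. Between runs the avirulent effect had r = 0.522 at 16 h and 0.617 at 24 h. A hypothesis is that the virulent strain draws a similar but later response, and effects from different runs gave an r at least 0.0439 higher for avirulent 16 h with virulent 24 h than with virulent 16 h, but a virulent effect that is merely stronger at 24 h would give the same. In the other direction the results were mixed: virulent 24 h was closer to avirulent 24 h (r = 0.593) than to 16 h (0.564) with the avirulent effect from the first run, and closer to 16 h (0.657, against 0.600) with it from the second. The contrast of 24 h with 16 h between strains called 0 probe sets by limma (925 at an unadjusted p under 0.05). The 925 are not far above the share of 0.05 of the 16188 tested that chance alone would give. Within each strain the contrast of 24 h with 16 h also called 0 probe sets by limma. At an unadjusted p under 0.05 there were 693 for the virulent and 353 for the avirulent effect, both below that share. The differences in count between 16 h and 24 h are therefore not shown as changes of single probe sets within a strain. The later response may be real but is not shown by these arrays.

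A difference in RNA quality, as read by the uneven actin ratio, could have entered the comparisons of infected with mock leaves. With the log2 ratio as a covariate 75.1% of the 3382 probe sets called for the avirulent strain in the mean over times kept their call and direction, and the median size of their change was 0.44 against 0.40 (median SE 0.12 against 0.10). This argues against that ratio as the whole source. Of 100 regroupings of the arrays within times, the real one included, 1 gave as many probe sets as virulent against mock (3834, highest other 1974). For avirulent against mock it was also 1 (3382, highest other 2228). A share under 1 in 100 cannot be reached with this number, so chance is made unlikely for both but is not excluded. Regroupings within times do not test an effect of the number runs. For avirulent against virulent the observed count was 0, which 100 of 100 must reach, so this test says nothing there; the highest other was 47.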
